A study of Mus musculus with 12 samples.

How the data were processed

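Pineal glands were measured on 12 Affymetrix mouse 430_2 arrays, 3 for each of 4 groups: control and Crx-/- glands at ZT6 and at ZT20. Per the labels, animals of both genders older than 2 months were kept in 12 h light and 12 h dark, dim red light was used for killing at ZT20, and 100 ng of RNA was amplified with the NuGEN Ovation kit. Groups were taken from the deposited titles and no sample was moved. Per the labels, the authors processed the arrays with GCOS, whose version is not stated, and the deposited values are the signal intensity of each probe set on a linear scale. The 2% trimmed means of the deposited signals ranged from 381.8 to 698.3, so the arrays had not been scaled to one another. The authors also deposited lists of genes up and down in Crx-/- glands, made with ChipInspector 2.1, which give a log2 fold change and a signed linear fold change for both times together.

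The deposited signals were quantile normalized between arrays, and the log2 of the signal plus 3.4, the 10th percentile of all signals, was used. Quantile normalization had been planned as an alternative to the authors' scaling. Since no such scaling was present it became the main setting, and the signals as deposited became an alternative chosen after seeing the data. Of 45101 probe sets 64 control features were left out. Probe sets were kept when at least 3 arrays were at or above the median (50th percentile) of their array, which left 24273. A symbol was given for 34945 probe sets, several symbols for 932 and none for 9160; those with several or none were not tested. Gene IDs of 34741 probe sets matched the reference gene table (assembly GRCm38.p6), which was used only for names and neighbours. Where a gene had several kept probe sets, that with the highest mean was tested, and 12379 genes were tested, 5272 of them with more than 1 kept probe set. The 27 Bacillus control probe sets, for which the glands hold no transcript, reached at most 16.4, and a group was treated as at background when all its arrays were at or below their level. Folds given as "at least" set the mean of the brighter group against that of the dimmer one, with each array below that level raised to it. The ratio of 5' to 3' probe sets was 0.169 to 0.337 for actin and 0.459 to 0.691 for Gapdh, with no overlap between the genotypes at ZT6 for either, and the array labelled control ZT20 replicate 3 had the highest of each. No value was negative or missing, and 0 pairs of arrays held identical values.

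Group means were fitted with limma 3.58.1 in R 4.3.3, with a trend in the prior variance. The contrasts were genotype over both times, genotype at ZT6 and at ZT20, time in each genotype, and the interaction. Tests were two-sided, p values were adjusted by the Benjamini-Hochberg method over the genes tested, and genes with an adjusted p under 0.05 were called. The 22 gene lists covered melatonin synthesis, cAMP-induced genes, adrenergic and cAMP signalling, phototransduction, photoreceptor structure, ribbon synapses, transcription factors, Hox genes, the clock, interferon, the cell cycle, oxidative phosphorylation, sex, and markers of astrocytes, microglia, endothelium, meninges, choroid plexus, brain neurons, oligodendrocytes, erythrocytes and muscle. The 19 lists with at least 5 tested genes were compared with the other genes by camera, with a preset correlation of 0.01 and again with an estimated one.

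Named genes followed a rule set before the data were examined. It took, over both times, the 12 called genes of largest change in each direction whose arrays did not overlap between genotypes at either time, and at each time the 5 of largest change in each direction. For time it took the 8 in each direction in each genotype whose arrays did not overlap, and for the interaction the 6 in each direction. Up to 4 called members of each list followed, and Crx, Tph1, Ddc, Aanat, Asmt, Hoxc4 and Otx2 were always included; Asmt and Adrb1 were not analysed here. The array labelled control ZT20 replicate 3 resembled the Crx-/- arrays, and the rule was applied again without it after this was seen.

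The fit was tested on simulated data with the spread of the 11 other arrays and 12368 genes. For genotype over both times it recovered 74.3% of genes changed by 0.5 on the log2 scale, 97.2% at 1 and 100% at 2. For genotype at ZT6 the shares were 52.9%, 84.3% and 98.4%, and for the interaction 9.86%, 68.9% and 97.1%. Of 19 simulated lists the 1 raised list was called and 0 others were. False calls numbered 6, 6 and 2 in the order given. The simulated spread left out the array labelled control ZT20 replicate 3, which the main fit kept. For genotype over both times 70, 71 and 59 of 12368 genes were changed, each independent of the others, whereas the main fit called 43.5% of genes. The recovered shares therefore do not hold for that fit. The list result does not vouch for the calls on the real lists. Their estimated correlation reached 0.618 with all 12 arrays, and 33 of 35 list calls were lost when it was used.

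Alternatives covered the scaling (as deposited, or centred on the 75th percentile), the pseudocount (1, or the 25th percentile, 15.3), the filter (none, or the 75th percentile), eBayes without a trend, array weights, replicate number as a block, only the compared groups in the fit, all kept probe sets, probe sets with shared-transcript suffixes left out, and each array left out in turn. Leaving out both the array labelled control ZT20 replicate 3 and Crx-/- ZT6 replicate 3 was added after seeing the data. At ZT20 alone, the deviations from the group means of same-numbered control and Crx-/- arrays correlated at r = 0.126, 0.130 and 0.176, each over 0.1, while other pairs there had r from -0.168 to 0.0401; the labels give no source for such a pairing. A fit of the ZT20 arrays with the number as a block was therefore added. Coordinates in the deposited lists were not used, since their genome build is not stated.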

Results

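Pineal glands of control mice (strain 129sv) and of Crx-/- mice, which lack a working copy of the photoreceptor and pineal transcription factor Crx, were profiled in the day (Zeitgeber time 6, ZT6) and in the night (ZT20). Each of the 4 groups held 3 arrays of separate biological replicates, as the labels give them, and 12 Affymetrix mouse 430_2 arrays were measured in all. The series therefore asks which pineal transcripts depend on Crx, and whether their day and night levels do. After the array's control features were left out, 24273 of 45037 probe sets passed the filter on dim signals, and 12379 genes were tested. The trimmed mean signal ranged from 381.8 on the array control ZT20 replicate 1 to 698.3 on Crx-/- ZT20 replicate 3. For arrays, the number of replicates limits the precision.

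The array labelled control ZT20 replicate 3 stood apart from its group. Its correlation across genes with the other control ZT20 arrays was 0.915 to 0.925, while it reached 0.970 to 0.989 with the Crx-/- ZT20 arrays. The remaining replicate pairs of the series lay between 0.979 and 0.992, and the remaining control arrays correlated with the Crx-/- arrays at 0.893 to 0.926. Genes are not independent replicates, so these values carry no test. Hoxc4, a homeobox cluster gene, had a log2 signal of 11.17 on this array, against 2.25 and 4.86 on the other control ZT20 arrays and 10.65 to 11.03 on the Crx-/- ZT20 arrays. The array was kept under its deposited label, and the counts of called genes in each comparison are given both with and without it.

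**Figure D1:**
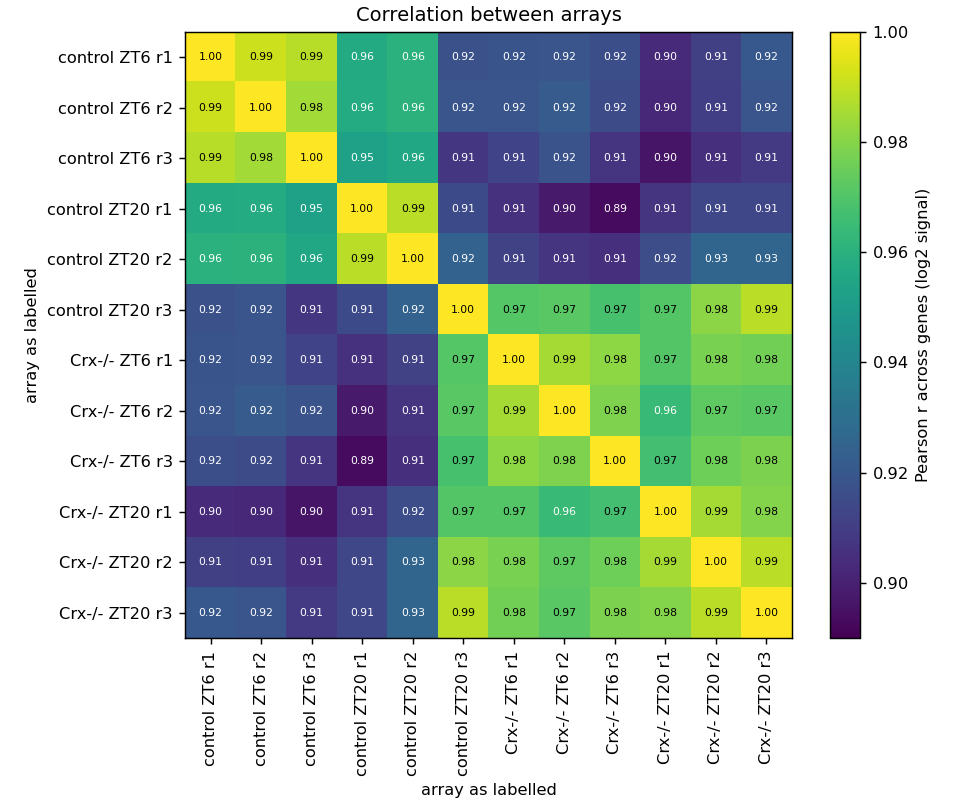
Pearson correlation across genes of log2 signals for each pair of the 12 arrays, ordered by group as labelled (both axes). The array labelled control ZT20 replicate 3 correlates at 0.970 to 0.989 with the Crx-/- ZT20 arrays and at 0.915 to 0.925 with its own group.

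Crx signal was present in every sample of both genotypes. The brighter of its probe sets gave deposited signals of 6529, 6786 and 7419 in control ZT6, 8329, 10050 and 8431 in control ZT20, 6359, 7729 and 6262 in Crx-/- ZT6, and 7436, 8020 and 8876 in Crx-/- ZT20 (replicates 1 to 3 of each). The dimmer probe set gave 2240, 2240 and 2478 in control ZT6, 2448, 3874 and 2246 in control ZT20, 1263, 1734 and 1477 in Crx-/- ZT6, and 1694, 2267 and 2439 in Crx-/- ZT20. By genotype, the log2 change of Crx was -0.08 ± 0.06 (SE) on the brighter probe set (limma, adjusted p = 0.320) and -0.61 ± 0.13 on the dimmer (adjusted p = 0.00352). On the normalized log2 scale the dimmer probe set lay at 11.8 and 11.93 on control ZT20 replicates 1 and 2. It lay at 11.03 on the array labelled control ZT20 replicate 3, and at 11, 11.18 and 11.01 on the Crx-/- ZT20 arrays. Where these probe sets lie relative to the deleted part of the gene is not known here, so neither of them settles a sample's label.

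The first comparison asked which genes differed by genotype on average over both times of day. Neurofilament light chain (Nefl), the RNA-binding protein Rbfox3 of mature neurons and the retinal GABA receptor subunit Gabrr2 were higher in Crx-/- glands. Their log2 changes were 3.97 ± 0.62, 2.48 ± 0.48 and 2.96 ± 0.39 (SE, n = 6 arrays against 6). The GABA receptor subunit Gabrd, the thioredoxin-like photoreceptor gene Nxnl1, adenylyl cyclase 3 (Adcy3) and the photoreceptor phosphatase Ppef2 were lower, with -4.55 ± 0.52, -3.02 ± 0.49, -2.55 ± 0.37 and -2.46 ± 0.30. Hoxc4 was higher by 4.99 ± 1.07 (adjusted p = 0.00329; at least 24.9-fold, with 2 of 3 control ZT20 arrays above background), and the developmental transcription factors Isl1, Prox1 and Neurod2 by 3.29 ± 0.51, 2.71 ± 0.52 and 2.49 ± 0.34. In all, limma called 3136 genes higher and 2246 lower at an adjusted p under 0.05, and 414 and 362 of these changed by at least 1 on the log2 scale. Leaving out the array labelled control ZT20 replicate 3 raised the counts to 3858 and 3058.

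Among genes whose arrays did not overlap between genotypes at both times, the largest rises after Nefl were in Gm20383 (3.78 ± 0.61), Fstl5 (3.33 ± 0.44), Slc7a14 (3.00 ± 0.47), Lgi2 (2.99 ± 0.37), Cntnap5a (2.97 ± 0.40), Atp13a5 (2.64 ± 0.37), Ube2ql1 (2.57 ± 0.39), Rimbp2 (2.37 ± 0.29) and Rbfox1 (2.34 ± 0.24). Falls after Gabrd included the RNase P subunit Rpp25 (-3.23 ± 0.42), the myogenic factor Myog (-3.01 ± 0.37), Slc23a4 (-2.87 ± 0.45), Gpr143 (-2.71 ± 0.52), Nrn1l (-2.63 ± 0.44), Mgarp (-2.56 ± 0.29), Susd3 (-2.48 ± 0.45) and C1ql3 (-2.32 ± 0.53). The adjusted p (limma) of these genes ranged up to 0.00462. There were 1994 such genes among 12379, where chance gives 0.5% of genes without overlap at both times in one direction, and 4709 without the array labelled control ZT20 replicate 3, where chance gives 1%. The control ZT6 signals of Nefl, Slc7a14, Cntnap5a and Ube2ql1, and the Crx-/- ZT20 signals of Gabrd, were at background level on all 3 arrays, so only lower bounds hold there and the order above does not rank these genes. With background in place of dimmer values, the rise at ZT6 was at least 15.6-fold for Nefl, 9.62-fold for Slc7a14, 6.465-fold for Cntnap5a and 6.81-fold for Ube2ql1, and at ZT20 Gabrd was at least 4.83-fold lower. Over both times the log2 change of Gabrd was then -3.81, a bound, and the rise of the other 4 was at least 11.1-fold, 5.77-fold, 4.00-fold and 4.68-fold. Background was exceeded by 1 of 3 arrays for Fstl5 in each control group, Rbfox3 in control ZT6 and Nxnl1 and Nrn1l in Crx-/- ZT20, and by 2 of 3 for Gabrr2 in control ZT6 and Gpr143 in Crx-/- ZT6. Their bounds over both times were 7.13-fold for Fstl5, 4.84-fold for Rbfox3, 7.13-fold for Nxnl1, 4.88-fold for Nrn1l, 6.345-fold for Gabrr2 and 5.24-fold for Gpr143. The same rule, without the array labelled control ZT20 replicate 3, named Hoxc4 (6.28 ± 0.33), the glycine receptor subunit Glra1 (5.68 ± 0.32) and Smtnl2 (5.10 ± 0.10) among rises, and Fads2b (-6.07 ± 0.18), Tal2 (-5.69 ± 0.20) and Ptpn20 (-5.50 ± 0.15) among falls. In that fit Glra1 was at background on all control arrays, Fads2b on all Crx-/- ZT20 arrays and Hoxc4 on 1 of 2 control ZT20 arrays, so these changes were at least 13.4-fold, 61.2-fold and 53.9-fold and have no rank.

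**Figure D2:**
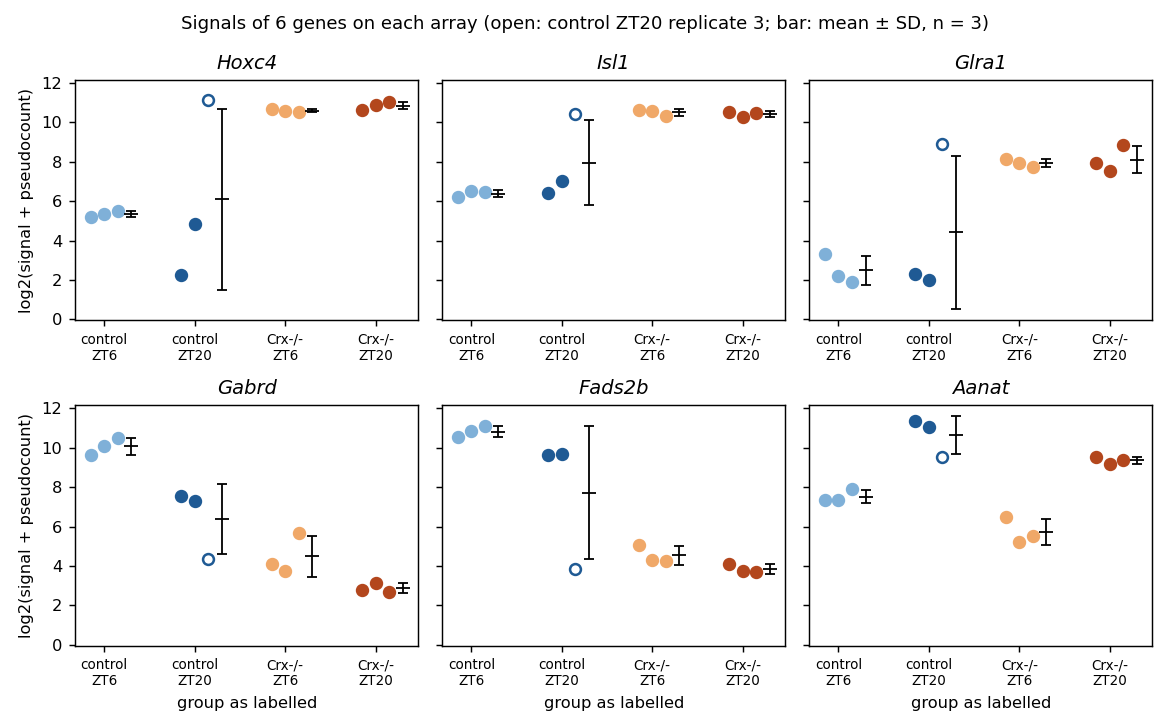
Log2 signal (with pseudocount) of 6 genes on each of the 12 arrays, by group as labelled; each point is an array, the open point is the array labelled control ZT20 replicate 3, and the bar is the mean ± SD of 3 arrays. For Hoxc4 the open point lies at 11.17 and the other control ZT20 arrays at 2.25 and 4.86.

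Genes of the phototransduction cascade were lower in Crx-/- glands: 14 of 25 fell, 3 rose and 8 did not pass (15 lower and 3 higher when adjusted over the list alone). Slc24a1, the sodium-calcium-potassium exchanger of rods, fell by 2.90 on the log2 scale (SE 0.45), the transducin subunit Gngt1 changed by -1.70 ± 0.38 and the short-wave opsin Opn1sw by -1.38 ± 0.27. Of 24 genes of outer segment, cilium and retinoid cycle, 10 fell and 3 rose, the same as adjusted over the list alone; Mpp4 (-2.04 ± 0.34), Lrat (-1.53 ± 0.32) and Tulp1 (-1.38 ± 0.21) fell, while the matrix proteoglycan Impg1 rose by 2.34 ± 0.39. Ribbon synapse genes fell in 12 and rose in 4 of 23 (12 and 5 adjusted over the list alone), with Lrit1 at -2.30 ± 0.22, Egflam at -1.19 ± 0.21 and Syt1 at -1.17 ± 0.30. By camera these lists were lower than other genes with adjusted p = 0.000415, 0.0141 and 0.00888. None of the 3 calls held with an estimated correlation, where the adjusted p = 0.423, 0.402 and 0.423.

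Markers of other cell types were higher in Crx-/- glands in the same comparison. All 6 oligodendrocyte genes rose (6 adjusted over the list alone), among them Sox10 (2.20 ± 0.29) and Mbp (1.42 ± 0.19). Of 18 fibroblast, meningeal and mural genes 16 rose (17 adjusted over the list alone), with Col3a1 at 1.05 ± 0.15 and Serping1 at 0.92 ± 0.15. Rises outnumbered falls in astrocyte genes (10 and 1 of 14, both adjusted over the list alone as well), microglial genes (9 and 1 of 15; 11 and 1 adjusted over the list alone), endothelial genes (8 and 0 of 14; 9 and 0 adjusted over the list alone) and choroid plexus and ependymal genes (8 and 1 of 13, unchanged when adjusted over the list alone). Exceptions were the radial glial fatty acid carrier Fabp7 (-1.65 ± 0.27) and the lysosomal Cd68 (-0.83 ± 0.17). Interferon and antigen presentation genes rose in 10 of 23 (12 adjusted over the list alone), with Oasl2 at 1.12 ± 0.23 and Gbp2 at 0.99 ± 0.18. The camera adjusted p was 0.000659 for oligodendrocyte, 7.89e-07 for meningeal, 0.00681 for astrocyte, 0.00681 for microglial, 0.00888 for endothelial, 0.0349 for choroid plexus and 0.0421 for interferon genes. With an estimated correlation none of these calls held (adjusted p = 0.402, 0.402, 0.423, 0.423, 0.423, 0.571 and 0.651 in that order), and the interferon call was lost without the array labelled control ZT20 replicate 3 (adjusted p = 0.113), where 13 rose and 3 fell. Removal of any of 6 other arrays also ended the interferon call, and that of Crx-/- ZT6 replicate 2 or Crx-/- ZT20 replicate 3 the choroid plexus call (adjusted p = 0.0571 and 0.0553).

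In the list for melatonin and tetrahydrobiopterin synthesis 5 of 10 genes fell and 3 rose, also when adjusted over the list alone (camera, adjusted p = 0.243). Aanat, the enzyme that sets the nightly melatonin rhythm, was lower by a log2 change of -1.53 ± 0.30 and sepiapterin reductase (Spr) by -0.99 ± 0.15. Tph1, the first enzyme of serotonin synthesis, was lower by -0.40 ± 0.08. The list's amine oxidases Maoa and Maob, which are not enzymes of melatonin synthesis, were higher by 0.71 ± 0.12 and 0.70 ± 0.17. Ddc (0.03 ± 0.04) and the pineal transcription factor Otx2 (0.11 ± 0.08) did not pass. Asmt, the last enzyme of melatonin synthesis, was not analysed here. Otx2, without the array labelled control ZT20 replicate 3, passed with 0.19 (limma, adjusted p = 0.00280) and Aanat changed by -1.82.

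Other lists were not called by camera over both times. Of 19 transcription factors of pineal and retinal development 7 rose and 3 fell (8 and 3 adjusted over the list alone), and of 20 clock genes 8 rose and 4 fell (unchanged when adjusted over the list alone), with Per3 at 1.13 ± 0.19. Among 23 cAMP-induced genes 6 rose and 3 fell (unchanged when adjusted over the list alone), with Egr3 at 1.19 ± 0.31 and Crem at -1.18 ± 0.24. Of 18 adrenergic and cAMP signalling genes 3 rose and 4 fell (unchanged when adjusted over the list alone), led by Adcy3, and the PACAP receptor Adcyap1r1 rose by 0.79 ± 0.12. Brain and habenular neuron genes rose in 6 and fell in 3 of 12 (7 and 3 adjusted over the list alone); Nefl and Calb2 (2.87 ± 0.46; at least 4.34-fold, as it was at background in control ZT6) rose, and the heavy neurofilament Nefh fell by 2.15 (SE 0.52). Cell cycle genes rose in 4 and fell in 1 of 16 (unchanged when adjusted over the list alone), and oxidative phosphorylation genes rose in 3 and fell in 3 of 29 (2 and 3 adjusted over the list alone). Of 6 erythrocyte genes only Bpgm changed (-0.46 ± 0.08), and the troponin Tnnc2, the only skeletal muscle gene tested, rose by 2.07 ± 0.54 (at least 3.22-fold, with 2 of 3 arrays of each control group above background). Hoxc4 and Hoxc5 (0.87 ± 0.18) were the only homeobox cluster genes tested; that list was drawn up knowing that the study names a gene of the cluster, so it is not independent evidence. None of the 4 genes that differ by sex passed (Eif2s3y, -0.99 ± 0.89). Leaving out the array labelled control ZT20 replicate 3 gave 7 higher and 8 lower cAMP-induced genes, 11 and 4 transcription factors, 4 and 3 cell cycle genes and 5 and 5 oxidative phosphorylation genes.

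By day, at ZT6, Glra1, Smtnl2, Hoxc4, the cholecystokinin receptor Cckbr and Nefl were higher in Crx-/- glands by log2 changes of 5.45 ± 1.35, 5.44 ± 0.94, 5.22 ± 1.52, 5.05 ± 0.55 and 4.97 ± 0.87 (SE, n = 3 against 3). The desaturase-like Fads2b, Gabrd, the helix-loop-helix factor Tal2, the acyltransferase Mogat1 and Trim15 were lower by -6.29 ± 1.14, -5.59 ± 0.74, -5.40 ± 1.24, -5.13 ± 0.94 and -5.10 ± 1.09. Control signals of Glra1 and Nefl were at background on all 3 arrays, so these rises were at least 13.7-fold and 15.6-fold. For Cckbr 1 of 3 control arrays was above background, and for Gabrd and Trim15 1 of 3 Crx-/- arrays was, which bounds the changes at 12.3-fold, 40.6-fold and 30.3-fold. The order of these 5 genes among the largest changes is therefore not known. Isl1, Prox1, Neurod2 and the bipolar cell factor Vsx1 rose by 4.12 ± 0.73, 3.52 ± 0.74, 3.36 ± 0.48 and 1.69 ± 0.33, and Aanat changed by -1.79 ± 0.42. The adjusted p (limma) of the genes named here ranged from 0.000218 for Cckbr to 0.0210 for Hoxc4, and the arrays of Glra1, Smtnl2, Hoxc4, Cckbr, Nefl, Fads2b, Gabrd, Tal2, Mogat1 and Trim15 did not overlap between the groups of 3.

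At ZT6 limma called 2338 genes higher and 1620 lower, of which 768 and 450 changed by at least 1. Without the array labelled control ZT20 replicate 3, which is not part of either group but enters the estimate of the spread, the counts were 3065 and 2319. Without control ZT6 replicate 1 the total was 2567. The ratio of 5' to 3' probe sets also differed at ZT6, from 0.459 to 0.548 for Gapdh and 0.169 to 0.219 for actin on the Crx-/- arrays against 0.590 to 0.636 and 0.248 to 0.283 on the control arrays, a separation that chance gives in 10% of cases for each ratio. Phototransduction genes fell in 10 and rose in 2 of 25 (11 and 2 adjusted over the list alone), with Slc24a1 at -3.57 ± 0.64, Ppef2 at -3.08 ± 0.42, Opn1sw at -1.87 ± 0.39 and the cone transducin Gnat2 at -1.63 ± 0.24. Of 24 photoreceptor structure genes 8 fell and 3 rose (9 and 3 adjusted over the list alone), with Impg1 at 3.21 ± 0.55 and Rom1 at -1.44 ± 0.14. Ribbon synapse genes fell in 9 and rose in 3 of 23 (11 and 3 adjusted over the list alone), and Lrit1 changed by -3.59 ± 0.32. The camera adjusted p of these lists was 0.00150, 0.0166 and 0.00903, and with an estimated correlation the adjusted p was 0.416 for each.

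Among markers at ZT6, 15 of 18 meningeal genes rose (16 adjusted over the list alone), with Col3a1 at 1.77 ± 0.21, as did all 6 oligodendrocyte genes (6 adjusted over the list alone), with Sox10 at 2.50 ± 0.41. Astrocyte genes rose in 8 and fell in 1 of 14 (10 and 1 adjusted over the list alone), microglial genes rose in 9 and fell in 1 of 15 (11 and 1), and endothelial genes rose in 4 and fell in 0 of 14 (8 and 0). The glutamate transporter Slc1a3 rose by 2.30 ± 0.49, Tmem119 by 1.33 ± 0.18 and Kdr by 1.13 ± 0.33, whereas Fabp7 changed by -1.74 ± 0.39 and Cd68 by -0.93 ± 0.24. The camera adjusted p was 1.46e-08 for meningeal, 0.00138 for oligodendrocyte, 0.00274 for astrocyte, 0.00354 for microglial and 0.00354 for endothelial genes, and each had an adjusted p = 0.416 with an estimated correlation. Choroid plexus genes rose in 3 and fell in 1 of 13 and were not called as a list (adjusted p = 0.148). With the array labelled control ZT20 replicate 3 left out, 10 endothelial and 7 of 12 choroid plexus genes rose. Brain neuron genes rose in 7 and fell in 2 of 12 (7 and 3 adjusted over the list alone; camera, adjusted p = 0.228). Rbfox3 rose by 3.56 ± 0.68 (at least 9.27-fold, with 1 of 3 control arrays above background), Camk2a by 2.39 ± 0.78 and Calb2 by at least 6.80-fold, while the nicotinic subunit Chrna3 changed by -1.16. The array Crx-/- ZT6 replicate 3 carried most of the Camk2a signal, with 11.33 against 7.58 and 7.30 on its replicates, and had the highest Rbfox3 of its group, 9.49 against 6.76 and 6.73.

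**Figure D3:**
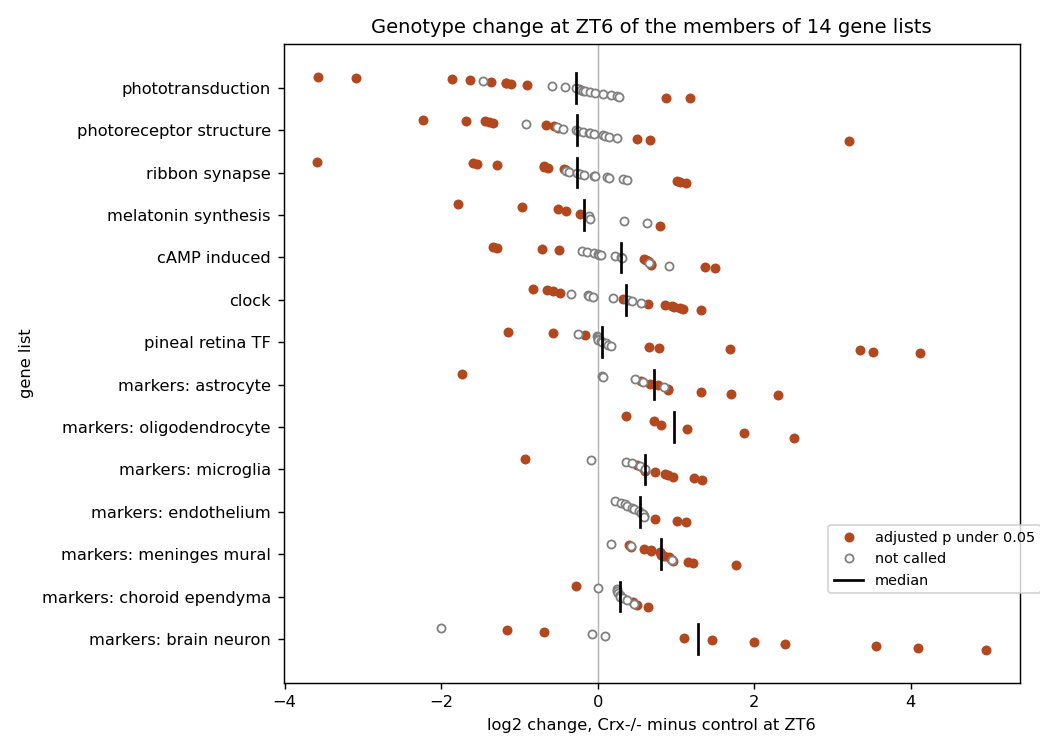
Log2 change by genotype at ZT6 (x axis) of each tested member of 14 gene lists (y axis); filled points passed an adjusted p of 0.05, open points did not, and the bar is the list's median. The medians of meningeal and oligodendrocyte markers lie at 0.807 and 0.974, and that of phototransduction genes at -0.277.

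By night, at ZT20, Gm20383, Nefl, Fstl5, Isl1 and D430019H16Rik were higher in Crx-/- glands by log2 changes of 3.26 ± 0.86, 2.97 ± 0.87, 2.79 ± 0.63, 2.46 ± 0.73 and 2.44 ± 0.66 (SE, n = 3 against 3). Ptpn20, Fads2b, Gabrd, the proto-oncogene Mycn and the neuronal tubulin Tubb3 were lower by -4.02 ± 1.16, -3.88 ± 1.14, -3.52 ± 0.74, -3.27 ± 0.91 and -3.15 ± 0.88. The adjusted p (limma) of these genes lay between 0.0262 and 0.0483. Hoxc4 (4.76 ± 1.52, adjusted p = 0.0579) and Aanat (-1.28 ± 0.42, adjusted p = 0.0616) did not pass. Without the array labelled control ZT20 replicate 3, the log2 changes were 4.77 for Gm20383, 4.33 for Nefl, 3.72 for Isl1, -6.03 for Ptpn20, -5.83 for Fads2b and -4.54 for Gabrd, and Hoxc4 (7.31) and Aanat (-1.84) passed with adjusted p = 1.52e-07 and 0.000284. Fads2b was at background in Crx-/- ZT20, so it was at least 12.2-fold lower with all arrays and 47.3-fold without that array. Fstl5, above background on 1 of 3 control arrays, was at least 4.935-fold higher, Gabrd at least 4.83-fold lower, and Hoxc4 without that array at least 76.6-fold higher. The Crx-/- ZT20 signals of Gabrd were at background on all 3 arrays, so its change of -4.54 is not a measured size.

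With all 12 arrays limma called 849 genes higher and 594 lower at ZT20, and 147 and 126 of these by at least 1. Without that array the counts were 2977 and 2429. They fell to 0 without control ZT20 replicate 1, Crx-/- ZT20 replicate 1 or Crx-/- ZT20 replicate 2, where 2667, 3227 and 3407 genes had an unadjusted p under 0.05 and to 1 without control ZT20 replicate 2. The total was 445, 508 or 735 without control ZT6 replicates 1, 2 or 3, and 705 or 915 without Crx-/- ZT6 replicates 1 or 2. In a fit of the ZT20 arrays alone it was 0 both without and with the replicate number as a block (limma; 2950 and 2969 genes at an unadjusted p under 0.05). The ZT6 and ZT20 comparisons share no array but use the same estimate of each gene's spread, so their calls are not independent. Higher in both were 576 genes (160.3 expected if independent), and lower in both were 366 (77.73 expected). Across genes the changes at the 2 times correlated at r = 0.771, and genes are not independent replicates. Leaving out control ZT20 replicate 3 gave 2002 and 1456 shared genes (737.8 and 455.4 expected) and r = 0.793. Whether a gene's genotype change differed between the times is tested by the interaction.

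Of 25 phototransduction genes 6 fell and 1 rose at ZT20 (11 and 1 adjusted over the list alone), with Slc24a1 at -2.23 ± 0.64, Gngt1 at -1.93 ± 0.54 and Pde6g at -1.32 ± 0.29. Photoreceptor structure genes fell in 6 and rose in 0 of 24 (8 and 1 adjusted over the list alone), with Mpp4 at -1.86 ± 0.48. Of the ribbon synapse genes 1 of 23 changed, Ctbp2 (0.39 ± 0.11; 0 adjusted over the list alone), and among adrenergic and cAMP signalling genes 2 of 18 fell and 1 rose (3 and 2 adjusted over the list alone). Oligodendrocyte genes rose in 4 of 6 (6 adjusted over the list alone; Sox10, 1.90 ± 0.41), meningeal genes in 2 of 18 (4), choroid plexus genes in 2 of 13 (6), interferon genes in 3 of 23 (6) and astrocyte genes in 2 of 14 with 1 fall (8 and 2). None of 15 microglial genes passed (5 higher and 1 lower adjusted over the list alone), C1qb having 0.62 ± 0.19, and none of 14 endothelial genes did. The camera adjusted p was 0.000217, 0.0335, 0.0268 and 0.0272 for the lists lower in Crx-/- glands in the order given, and 0.00114, 0.00173, 0.0268, 0.0268, 0.0423 and 0.0445 for oligodendrocyte, meningeal, choroid plexus, interferon, astrocyte and microglial genes. No call held with an estimated correlation (lowest adjusted p = 0.450). The adrenergic, interferon and microglial calls were lost without the array labelled control ZT20 replicate 3 (adjusted p = 0.0731, 0.0930 and 0.141). Without Crx-/- ZT20 replicate 2 only the phototransduction, oligodendrocyte and meningeal calls were left, 3 of 10 (adjusted p of the lost ones, 0.0648 to 0.109). Removing control ZT20 replicate 1 ended the astrocyte and choroid plexus calls, control ZT20 replicate 2 the structure, astrocyte and microglial calls, and Crx-/- ZT20 replicate 3 the astrocyte and choroid plexus calls. The microglial call was also lost without any 1 of the Crx-/- ZT6 arrays (adjusted p = 0.0577 to 0.0619). With control ZT20 replicate 3 left out more genes passed: 16 phototransduction genes fell and 2 rose, 11 and 4 structure genes, 13 and 4 ribbon synapse genes, and 6 and 3 adrenergic genes. Rises then numbered 6 of 6 oligodendrocyte, 14 meningeal, 7 of 12 choroid plexus, 9 interferon (2 fell), 11 astrocyte (2 fell), 5 microglial (1 fell) and 4 endothelial genes. The transcription factors were then called as higher by camera (10 rose and 4 fell, adjusted p = 0.0297), and 6 cAMP-induced genes rose and 7 fell, against 0 and 0 with all arrays. In the melatonin list Spr (-1.01 ± 0.21), Tph1 (-0.40 ± 0.12) and Pcbd1 (-0.38 ± 0.11) fell and the amine oxidase Maoa rose by 0.63 ± 0.17 (4 lower and 4 higher of 10 adjusted over the list alone, and 5 and 4 passed without that array).

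In control glands, the log2 signal of Aanat rose from 7.52 ± 0.31 at ZT6 to 10.64 ± 0.98 at ZT20 (SD, n = 3). The log2 change was 3.11 ± 0.42 (SE; limma, adjusted p = 0.000713). Cckbr (4.71 ± 0.55), the receptor Gpr3 (3.79 ± 0.40), Gabrr2 (3.21 ± 0.55), Shisal1 (3.13 ± 0.30), the glycine transporter Slc6a5 (2.88 ± 0.28), Tunar (2.83 ± 0.73) and Nefl (2.81 ± 0.87) were higher at night as well. Lower at night were the chemokine Cxcl9 (-4.45 ± 1.03), the neuropeptide Y receptor gene Npy6r (-4.31 ± 0.44), the calcium channel subunit Cacnb2 (-4.17 ± 0.32), Clca1 (-4.02 ± 0.58), Gabrd (-3.69 ± 0.74), Nrxn3 (-3.21 ± 0.22), the photoreceptor gene Pcare (-3.03 ± 0.44) and Ppp2r2b (-2.97 ± 0.30). Their adjusted p was at most 0.0459, and the 3 arrays of each time did not overlap. Against background, Gpr3 was at least 12.46-fold higher at ZT20, and Npy6r at least 15.3-fold lower. Cckbr, with 1 of 3 ZT6 arrays above background, rose at least 9.77-fold and Gabrr2, with 2 of 3, at least 6.16-fold. Cxcl9 and Clca1, with 1 and 2 of 3 ZT20 arrays above it, fell at least 7.65-fold and 14.15-fold. When the array labelled control ZT20 replicate 3 was left out, Cxcl9 fell at least 7.05-fold and Clca1 by 9.28-fold. Nefl rose at least 3.494-fold, but its ZT20 log2 signals were 4.48 and 4.75 on replicates 1 and 2 against 8.67 on replicate 3. Values against background set no order among these genes. Nefl, without the array labelled control ZT20 replicate 3, changed by 1.44, which is no measured size since its ZT6 signals were at background. Gabrd then changed by -2.68, Tunar by 4.02 and Aanat by 3.69.

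Genes induced by cAMP rose at night in control glands: 10 of 23 were higher and 0 lower (12 and 0 adjusted over the list alone). The deiodinase Dio2 rose by 2.40 ± 0.30, the nuclear receptor Nr4a3 by 2.07 ± 0.41 and the phosphodiesterases Pde10a and Pde4d by 1.43 ± 0.31 and 1.22 ± 0.12. The camera adjusted p was 8e-08, and the call held with an estimated correlation (adjusted p = 0.0107), though not without the array labelled control ZT20 replicate 3 (adjusted p of 0.0748 at the lowest of any list). Of 20 clock genes 4 rose and 4 fell (unchanged when adjusted over the list alone; camera, adjusted p = 0.358), with Nr1d1 at -1.86 ± 0.18, Cry1 at 1.37 ± 0.13, Per2 at 1.14 ± 0.19 and Per1 at 1.01 ± 0.18. Phototransduction genes fell in 12 and rose in 0 of 25 (unchanged when adjusted over the list alone), with phosducin (Pdc) at -2.46 ± 0.33, Ppef2 at -2.26 ± 0.42 and Opn1sw at -1.56 ± 0.39. Their camera adjusted p was 8.92e-06, with adjusted p = 0.5 with an estimated correlation. Of 18 meningeal genes 10 rose (13 adjusted over the list alone), with Tagln at 1.38 ± 0.21 and Col3a1 at 1.02 ± 0.21; the camera adjusted p was 8e-08, and adjusted p = 0.374 with an estimated correlation. After removal of the array labelled control ZT20 replicate 3, 13 cAMP-induced genes rose, 12 phototransduction genes fell and 2 rose, 9 meningeal genes rose, and 8 transcription factors fell and 3 rose (4 and 3 with all arrays). Adenylyl cyclase 1 (Adcy1) fell by 2.06 (SE 0.21), and Crx itself rose by 0.46 ± 0.08 (adjusted p = 0.00358).

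In control glands limma called 880 genes higher and 1118 lower at night, and 201 and 225 by at least 1. Leaving out control ZT20 replicate 3 gave 1485 and 1620. Without control ZT6 replicates 1, 2 or 3 the total was 953, 1128 or 998. Values of the 2 times did not overlap in 4544 of 12379 genes, where chance gives 10%, and in 7200 without control ZT20 replicate 3, where it gives 20%.

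In Crx-/- glands Aanat rose at night, from 5.74 ± 0.65 to 9.36 ± 0.18 (SD, n = 3), a log2 change of 3.63 ± 0.42 (SE; limma, adjusted p = 0.00132). The G protein subunit Gng4 (3.39 ± 0.61), 9130409I23Rik (2.69 ± 0.35), Slc6a5 (2.63 ± 0.28), Vil1 (2.56 ± 0.47), Pde10a (2.54 ± 0.31), Cabp1 (2.51 ± 0.45) and Lrit1 (2.44 ± 0.32) were also higher. The clock repressor Nr1d1 (-2.83 ± 0.18), Cacnb2 (-2.68 ± 0.32), Ppp2r2b (-2.49 ± 0.30), Rprm (-2.31 ± 0.38), Cdh8 (-2.21 ± 0.20), Pdc (-2.20 ± 0.33), the nicotinic subunit Chrna6 (-2.06 ± 0.33) and Pcare (-1.96 ± 0.44) were lower, each without overlap between the times. With 2 of 3 arrays of the dimmer time above background, 9130409I23Rik, Cacnb2 and Pcare changed at least 6.21-fold, 5.93-fold and 3.115-fold. Cry1 rose by 1.63 ± 0.13 and the clock output factor Dbp changed by -1.15 ± 0.16. Of the cAMP-induced genes 4 of 23 rose and 0 fell (5 and 0 adjusted over the list alone), Fosl2 and Pde4b among them (1.04 ± 0.12 and 1.01 ± 0.13). The camera adjusted p was 3.18e-05, and it was 0.0452 with an estimated correlation, a call that was lost without the array labelled control ZT20 replicate 3 (lowest adjusted p of any list, 0.186). Phototransduction genes fell in 6 and rose in 0 of 25 (10 and 0 adjusted over the list alone), with Cngb3 at -1.29 ± 0.13 and Cngb1 at -1.26 ± 0.25; the camera adjusted p was 2.48e-07, and adjusted p = 0.532 with an estimated correlation. Once the array labelled control ZT20 replicate 3 was left out, 13 phototransduction genes fell, 6 cAMP-induced genes rose, and 5 clock genes rose and 4 fell (1 and 3 with all arrays).

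In all 86 genes were higher and 108 lower at night in Crx-/- glands (limma), 42 in each direction by at least 1. Without the array labelled control ZT20 replicate 3, which is in neither group, the counts were 321 and 437. Without Crx-/- ZT6 replicates 1, 2 or 3 the total was 103, 87 or 122, and without Crx-/- ZT20 replicates 1 or 2 it was 87 or 84. Without control ZT6 replicates 2 or 3 it was 129 or 128. Values of the 2 times did not overlap in 2730 of 12379 genes, where chance gives 10%. Both genotypes shared 62 genes higher at night (6.11 expected if independent) and 62 lower (9.75 expected), and the changes correlated across genes at r = 0.439. With the array labelled control ZT20 replicate 3 left out they shared 214 and 232 genes (38.54 and 57.24 expected), with r = 0.444. The comparisons by time also use the same estimate of each gene's spread, so their calls are not independent.

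**Figure D4:**
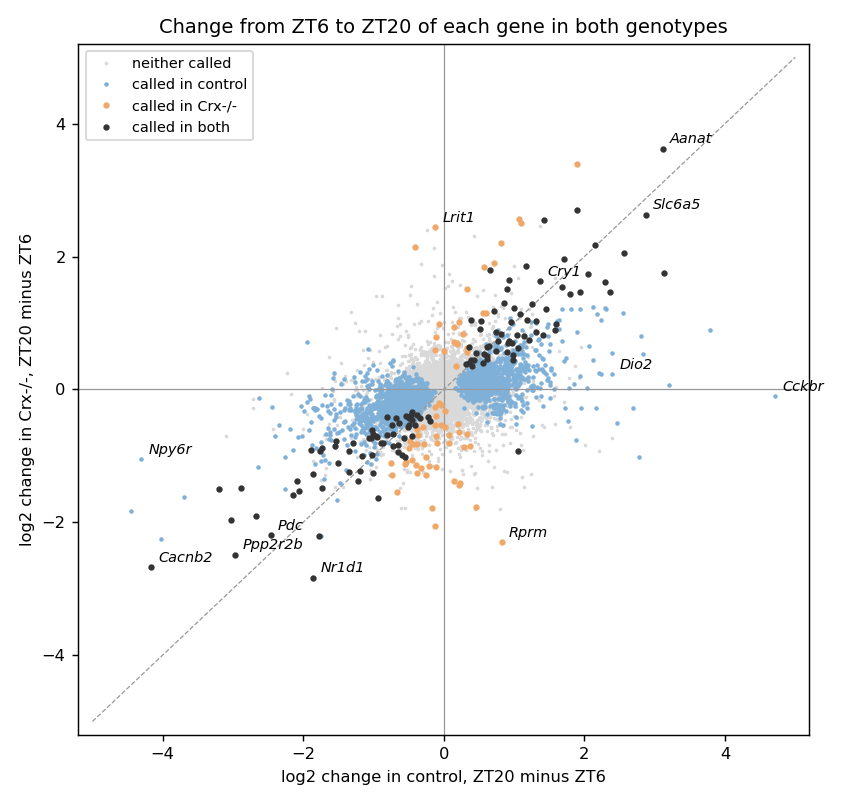
Log2 change from ZT6 to ZT20 of each tested gene in control (x axis) and in Crx-/- glands (y axis), with genes past an adjusted p of 0.05 coloured by the genotype in which they passed; the dashed line marks equal change. Aanat lies at 3.11 and 3.63 and Nr1d1 at -1.86 and -2.83.

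The interaction tests whether the day to night change differed between the genotypes. Cckbr, which rose at night in control glands, had a log2 signal of 7.90 ± 0.11 at ZT20 in Crx-/- glands (SD, n = 3), and its interaction was -4.82 ± 0.78 (SE, log2; limma, adjusted p = 0.0485). Only 1 of 3 control ZT6 arrays was above background for Cckbr, and with background in place of the dimmer values the interaction was -3.39; for Rprm, with 2 of 3, it was -2.89. Rprm (-3.13 ± 0.53), the carboxypeptidase Cpz (-1.99 ± 0.28), the sphingosine kinase Sphk2 (-1.61 ± 0.19), the ETS factor Etv5 (-1.57 ± 0.28) and the collagen Col5a2 (-1.46 ± 0.26) also fell further, or rose less, at night in Crx-/- glands. Lrit1 (2.57 ± 0.45), Fam122b (1.60 ± 0.29), 4930526L06Rik (1.59 ± 0.28), Samsn1 (1.49 ± 0.24), 0610009L18Rik (1.39 ± 0.23) and the thymocyte factor Tox (1.38 ± 0.24) changed the other way. The second probe set of Sphk2 had the opposite sign. The same rule, applied without the array labelled control ZT20 replicate 3, named E2f8 (-4.82 ± 0.62), Cpm (-4.70 ± 0.42) and Evi2a (-4.68 ± 0.28) among negative interactions. Among positive ones it named Slc15a1 (2.51 ± 0.32) and Adgrb3 (2.46 ± 0.42). For Aanat the interaction was 0.51 ± 0.59 (adjusted p = 0.760; -0.05 without the array labelled control ZT20 replicate 3), and for the clock genes Dbp and Arntl -0.95 ± 0.22 and 0.65 ± 0.16 (adjusted p = 0.0981 and 0.110).

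Limma called 14 genes with a positive and 15 with a negative interaction, with adjusted p from 0.0203. Without the array labelled control ZT20 replicate 3 the counts were 280 and 482. Without control ZT6 replicate 2 the count was 1, without control ZT20 replicate 1 it was 11, without Crx-/- ZT6 replicate 3 it was 16, and it was 0 without each of the remaining arrays, where at least 1218 genes had an unadjusted p under 0.05. The cAMP-induced genes rose less at night in Crx-/- glands as a set (median -0.41, camera adjusted p = 0.0126; adjusted p = 0.316 with an estimated correlation), although 0 of 23 passed singly (0 higher and 2 lower adjusted over the list alone), Dio2 having -2.16 ± 0.42. Meningeal and mural genes did so as well (median -0.49, camera adjusted p = 1.5e-07; adjusted p = 0.542 with an estimated correlation), with Col1a1 (-0.74 ± 0.13) and Col1a2 (-0.70 ± 0.11) the 2 of 18 that passed (0 higher and 8 lower adjusted over the list alone). The channel subunit Cngb3 changed by -1.04 ± 0.18. By genotype at ZT6, 8 of 23 cAMP-induced genes were already higher in Crx-/- glands and 4 lower (median 0.296, camera adjusted p = 0.228). By genotype at ZT20, 0 were higher and 0 lower (median -0.185, camera adjusted p = 0.214). The lesser rise of this set therefore includes a higher level by day. After the array labelled control ZT20 replicate 3 was left out, 4 cAMP-induced, 4 meningeal and 5 phototransduction genes had a negative interaction.

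With the signals as deposited, without scaling between arrays, the split of calls moved. Over both times 2076 genes were higher and 662 lower in Crx-/- glands, against 3136 and 2246 after quantile normalization. At ZT20 the counts were 34 and 38 against 849 and 594. By time they were 72 and 463 against 880 and 1118 in control, and 34 and 26 against 86 and 108 in Crx-/- glands. The median of all genes moved to 0.17 over both times, 0.26 at ZT20, -0.28 by time in control, -0.14 by time in Crx-/- glands and 0.14 for the interaction. Centring on the 75th percentile gave interaction counts of 28 and 20 against 14 and 15.

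The study deposited its own lists of genes up and down in Crx-/- glands for both times together, computed from the same arrays with ChipInspector, so the comparison is one of processing. Of 714 and 512 entries 490 and 356 genes could be tested. The sign was the same in 489 and 350 of these, and 477 (97.4%) and 317 (89.0%) were called in the same direction, while 1 and 2 were called in the opposite one. The deposited and fitted log2 changes correlated at r = 0.944 and rho = 0.909 across the 845 genes. Both lists were pooled, with a deposited cutoff of 1 in each direction, so these values reflect the shared sign as well as the size. Examples are Hoxc4 (4.13 deposited), Isl1 (2.51), Smtnl2 (3.96), Fads2b (-4.12), Ptpn20 (-3.97) and Gabrd (-2.99). Of the 776 genes called with a log2 change of at least 1, 527 were in a deposited list. Without the array labelled control ZT20 replicate 3, 99.2% and 96.4% were called in the same direction.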

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

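The tests of the array labelled control ZT20 replicate 3 and of the cell type markers were chosen only after those results were seen, whereas the counts of other splits of the samples were planned.

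The day to night change differed between the genotypes, by the interaction test of limma, in 29 genes. The log2 interaction was 2.57 for Lrit1, 1.60 for Fam122b, 1.59 for 4930526L06Rik, 1.49 for Samsn1, 1.39 for 0610009L18Rik and 1.38 for Tox. It was -4.82 for Cckbr (-3.39 with background in place of dimmer values), -3.13 for Rprm, -1.99 for Cpz, -1.61 for Sphk2, -1.57 for Etv5, -1.46 for Col5a2, -1.04 for Cngb3, -0.74 for Col1a1 and -0.70 for Col1a2. By camera the cAMP-induced genes (median -0.41) and the meningeal and mural genes (median -0.49) differed as well, with adjusted p = 0.316 and 0.542 with an estimated correlation. Of 100 splits, 7 gave at least 29 genes, the highest other 1962. For lists 93 gave at least 2, the highest other 12. The splits exchanged arrays between the times within each genotype, which can turn a day to night change shared by both into an interaction. They therefore cannot decide on chance, which is not excluded. Without the array labelled control ZT20 replicate 3 the count was 762, and it was 0 without control ZT6 replicate 1, where 1218 genes had an unadjusted p under 0.05.

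The array labelled control ZT20 replicate 3 resembled the Crx-/- arrays. On an axis from 0 for control to 1 for Crx-/- glands, drawn from 5474 genes at ZT6, it lay at 0.936, the other control arrays between -0.0274 and 0.0274, and the Crx-/- ZT20 arrays between 0.967 and 1.02. Crx-/- RNA mixed into a control sample is argued against, since a median of -0.841% of the signal gap was kept in 54 genes lowered in Crx-/- glands (interval -1.85 to 0.00414), where a mixture was to keep over 10%. An exchange within the series is argued against as well, since the lowest Crx-/- array lay at 0.967. A wrong label, or an exchange with a sample outside the series, may account for the array and stays open. Its 0.936 lay just below the Crx-/- range, but the other arrays set the 0 and 1 of the axis and this array did not. That gap therefore cannot decide, and no biological explanation was tested.

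Markers of other cell types were higher in Crx-/- glands, with medians at ZT6 from 0.29 for choroid plexus, a list not called at ZT6 (camera, adjusted p = 0.148), to 1.14 for oligodendrocyte genes not held by another list, and the other calls were lost with an estimated correlation (adjusted p = 0.416). A lower share of pinealocyte RNA as the whole cause stays open. The 6 lists differed by more than their members' spread (permutation p = 0.00081, and 0.00182 for 54 genes of middle brightness). The permutation treated genes as independent, while the estimated correlation within these lists was 0.317 to 0.618, so it cannot decide. Tissue carried over at random is only weakly argued against by an exact one-sided permutation p of 0.005, with 2 of 400 arrangements as large. The 6 lists and the direction were chosen after the rise was seen, so this p may be too small. The normalization is argued against by a difference of at least 0.557 ± 0.111 (SE, n = 3 against 3) under 3 scalings. A genotype effect, carry-over that differed systematically between genotypes, or the lower 5' to 3' ratio of the Crx-/- arrays at ZT6 may remain, and none of these was tested.

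For genotype over both times, as for the interaction, the 100 splits were the real one and a random sample of the others. Only 1 of them, the real one, gave 5382 genes, and the highest other gave 4673, so chance is unlikely but not excluded. That other split exchanged control ZT20 replicate 3 with Crx-/- ZT20 replicate 3. For the lists 5 of 100 splits gave at least 10, the highest other 12, so chance is not excluded. For the deposited lists 2 of 100 splits gave at least 794 genes in the deposited direction, the highest other 797, but the lists were made from the same arrays under the real labels, so this does not test chance. For the remaining comparisons the 10 splits are too few for a share under 0.05. At ZT6 the real split gave 3958 genes and the highest other 0 (limma; at most 485 at an unadjusted p under 0.05), with 1 as large, and 8 lists against 10, with 3 as large. At ZT20 it gave 1443 genes against 231, and 10 lists against 9, with 1 as large for each. By time in control it gave 1998 genes against 0 (at most 1572 unadjusted), with 1 as large, and 3 lists against 12, with 9 as large. By time in Crx-/- glands it gave 194 genes against 0 (at most 819 unadjusted), with 1 as large, and 2 lists against 5, with 5 as large.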

How the results depend on the processing

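The signals as deposited, the fit without both doubted arrays, the block at ZT20 alone and the second use of the rule for named genes were chosen after seeing the data; all other alternatives were planned, and planned quantile normalization was the setting reported. Of 8279 tests of 342 called gene and comparison pairs, 6798 kept the call, 1480 lost it and 1 changed sign, and of the list tests 33 of 35 lost the call with an estimated correlation. The reversed value was Rarres2 at ZT6, -0.45 without probe sets of shared suffix, where another probe set was tested. Signals near background limit the folds of dim genes. By correlation, replicate numbers paired control and Crx-/- arrays of the same time at ZT20 only. Between the Crx-/- arrays of ZT6 and ZT20 the same-number pairs had r = 0.0896, 0.0571 and 0.173. Other pairs there had r from -0.137 to 0.0509. Over the series 5 of 18 same-number pairs had r over 0.1, with a median of -0.00456 against 0.0153 for other pairs. Where no reason is given, the cause was not tested.

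A log2 change of at least 1 left 776 genes over both times, 1218 at ZT6, 273 at ZT20, 426 by time in control and 84 by time in Crx-/- glands. Signals as deposited gave 2738, 1272, 72, 535, 60 and 4 (interaction), with 5 lists by time in control, 4 for the interaction and 84.5% of the down list. The 75th percentile filter, with fewer genes tested, gave 3510 over both times, 2531 at ZT6 and 6 for the interaction, with 3 lists at ZT20 and 5 by time in control. Centring on the 75th percentile gave 116 by time in Crx-/- glands and 48 for the interaction, with 5 lists at ZT20. Array weights gave 6125 at ZT6, 7164 at ZT20, 5772 and 911 by time, 1762 for the interaction, and 99.6% and 96.6% of the up and down lists. All kept probe sets gave 9213, 6305, 2364, 302 (time in Crx-/-) and 14 (interaction), with 6 lists by time in control and 7 for the interaction. No filter gave 765 at ZT20 and 1 for the interaction, with 7 lists by time in control. Without a trend ZT20 gave 948. For the interaction a pseudocount of 1 gave 5, the block 1, and no shared suffix 57, with 4 lists, and 3 lists at ZT20. The pseudocount 15.3 moved r to 0.955. Only the compared groups gave 0 at ZT20 (limma; 2950 unadjusted), also with the block (0; 2969 unadjusted; 11 lists), 895 by time in control and 407 in Crx-/- glands. Without both doubted arrays the counts were 5540 at ZT20, 3269 and 795 by time in control and Crx-/- glands, and 927 for the interaction, with 96.4% of the down list. The estimated correlation left 0 lists over both times, 0 at ZT6, 0 at ZT20, 1 and 1 by time and 0 for the interaction (camera).

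With 1 array left out the counts ranged from 4419 to 6916 over both times, 2567 to 5384 at ZT6, 0 to 5406 at ZT20, 953 to 3105 by time in control, 84 to 758 in Crx-/- glands and 0 to 762 for the interaction. Lists ranged from 8 to 10, 8 to 9, 3 to 10, 3 to 9, 2 to 2 and 2 to 4, the up list from 94.7% to 99.2%, the down list from 82.3% to 96.4%, and r from 0.939 to 0.946.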

Other observations

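The receptor, collagen and channel families were picked because their members were seen to change, so no test is given for them and only counts are. The tests of the sex-linked genes and of the sex explanation were chosen only after the values were seen; the second brain list and the test of genes near Crx were written before. Subunits of neurotransmitter receptors differed between genotypes at ZT6, where the ratios of 5' to 3' probe sets differed as well (Gapdh 0.459 to 0.548 on Crx-/- arrays against 0.590 to 0.636, and actin 0.169 to 0.219 against 0.248 to 0.283). Among 11 GABA and glycine receptor subunits 5 rose and 3 fell, Gabrr2 by 4.53 ± 0.55 and Gabrb2 by 2.99 ± 0.52 (log2, SE, n = 3 against 3) upward, with Gabrd at -5.59 ± 0.74 and Gabrr1 at -3.94 ± 0.70; against background these were at least 15.4-fold for Gabrr2, 40.6-fold for Gabrd and 10.05-fold for Gabrr1. Of 11 glutamate receptor subunits 9 rose and 0 fell, with Gria2 at 3.56 ± 0.94 (at least 10.6-fold) and Grin2c at 3.06 ± 0.55. Nicotinic subunits fell in 5 of 7 and rose in 1, with Chrna7 at -2.42 ± 0.52, Chrna5 at -1.95 ± 0.34 and Chrna6 at 2.60 ± 0.33. At ZT20 the GABA and glycine, glutamate and nicotinic subunits rose in 0, 3 and 0 and fell in 1, 0 and 1, and without the array labelled control ZT20 replicate 3 they rose in 5, 6 and 1 and fell in 2, 0 and 5. Without the array Crx-/- ZT6 replicate 3, which stood apart with high brain neuron genes, 4 GABA and glycine subunits rose and 3 fell of 9, 7 glutamate subunits rose and 0 fell, and 1 nicotinic subunit rose and 4 fell at ZT6.

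Collagen chains rose in 20 and fell in 3 of 32 at ZT6, in arrays with the same difference in 5' to 3' ratio, with Col11a1 at 2.29 ± 0.28, Col5a2 at 2.03 ± 0.18 and Col7a1 at -2.01 ± 0.47. Voltage-gated potassium channel subunits rose in 8 and fell in 1 of 14, with Kcna2 at 2.08 ± 0.21 and Kcns3 at 1.55 ± 0.30. At ZT20 8 collagen chains and 3 channel subunits rose and 0 of either fell, and without the array labelled control ZT20 replicate 3 these were 20 and 4 rises with 2 falls in each. Without Crx-/- ZT6 replicate 3, 19 collagen chains rose and 3 fell of 31 at ZT6, and 6 potassium channel subunits rose and 0 fell of 13. Fibroblast, meningeal and mural markers, which include 3 of the collagen chains, rose in 15 of 18 in the same comparison, so the collagen result is not independent of the marker result. The direction of each family's median was the same under 3 scalings, but with signals as deposited only 3 potassium channel subunits were called, all higher.

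Brain neuron genes were high on the array Crx-/- ZT6 replicate 3. Brain RNA in that sample is a candidate source: of 35 abundant brain genes listed before they were looked at, 1 of them also an astrocyte marker, 23 were tested, and their median excess of 0.38 lay at percentile 100 of random lists of like brightness (95th percentile 0.0495). Camk2n1 had 12.06 there against 10.97 and 10.83, and Calb1 9.83 against 6.60 and 7.53. The sex of the animals is only weakly argued against by arrays with signals of both sexes. The Crx-/- ZT20 arrays reached a median share of -0.317 of the gap between Crx-/- ZT6 replicates 1 and 3, but they differ in time. Crx-/- ZT6 replicate 2, of the same time, reached -0.216 but is a single array. Whether the gland's own neurons differed between these samples was not tested.

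Xist and the Y-linked Eif2s3y were both high on 10 arrays, and the labels give both genders. The exceptions were Crx-/- ZT6 replicate 1, with an Eif2s3y log2 signal of 5.29, and Crx-/- ZT6 replicate 3, with an Xist log2 signal of 8.38. On the 10 arrays these signals point to RNA of both sexes, and so of more than 1 animal per array. How many glands were pooled is not given. Of the 100 tested genes nearest to Crx 33% were called at ZT6, against 32% of other genes (Fisher exact one-sided p = 0.45), so an excess near the targeted locus was not seen.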
